A study of Arabidopsis with 12 samples.

How the data were processed

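Arabidopsis seedlings of the wild type Col-0 and of the bzip59 insertion mutant were grown in continuous white light for 7 days, and part of each genotype then received 2 h of shade at a red to far-red ratio of 0.65, per the labels' protocols. RNA came from whole seedlings, was selected on oligo(dT) beads and was reverse transcribed with random primers for Illumina sequencing, per the labels' protocols. Strandedness was not stated. Reads were trimmed with fastp and cutadapt and aligned with HISAT2 to TAIR10, and differential expression was computed with DESeq2, per the submitters' processing notes, which give no versions. The values deposited by the authors were TPM per transcript, per the file headers, and the tool that computed TPM was not given in the sources used here.

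The table held 12 library columns and 4 group mean columns. The group means equalled the means of their 3 libraries within 3.3e-06 TPM and were not used. TPM values of 54013 transcripts were summed to 32833 genes, of which 32548 matched a RefSeq locus tag. RefSeq records (TAIR10.1) served for symbols, biotypes, neighbouring genes and gene length in a check for length trends. No coordinates are printed because the alignment used another annotation release. Column sums ran from 937165 to 955765 TPM, and the sources do not say which transcripts account for the remainder of the TPM total. All 8 housekeeping genes examined were above 0 in every library, and 195 genes with a mean of at least 5 TPM had a 0 in some library.

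Tests used limma 3.58.1 with an intensity trend on log2(TPM + 1) in R 4.3.3, with the package data.table in version 1.17.8. Genes with a mean of at least 1 TPM over the 12 libraries were tested, 19693 in all. A single fit with 4 group means gave 5 contrasts, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were shade against white light in each genotype, bzip59 against Col-0 in each light, and the interaction, which is the shade effect in bzip59 less that in Col-0. Fold changes are on the log2(TPM + 1) scale and understate changes of genes with low values. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

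The 29 gene lists covered early shade avoidance, auxin response, auxin synthesis and transport, brassinosteroid, gibberellin, ethylene, cytokinin, jasmonate, salicylate and immunity, abscisic acid and dehydration, the circadian clock, light signalling, light harvesting and flavonoids. The others covered XTH cell wall enzymes, expansins, PRE family bHLH genes, bZIP group I, LBD callus genes, sulfur, iron, and nitrate and phosphate responses, heat shock, rapid touch, wound and cold responses. The last 5 lists were markers of seed storage, green tissue, root, root hair and dividing cells. All 384 list entries were found in the table, and 8 entries are printed by locus because no source held their name. Each list was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 29 lists within a contrast. Calls are also given adjusted over the list alone. Camera with an estimated correlation and fry were the alternatives. Fry tests whether the genes of a list move, on balance, to the same side, and does not compare them with other genes.

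Tests, contrasts, gene lists, thresholds and the rule for named genes were chosen before the data were examined. In each pairwise comparison the rule named AT2G31370 (bZIP59), then the 8 called genes with the largest rise and the 8 with the largest fall among those whose libraries did not overlap in TPM. It then named up to 3 called members of each list, by smallest p. For the interaction it named up to 8 genes per direction, or, with fewer than 4 past the threshold, the 4 genes with the smallest unadjusted p, reported as failing. A gene named by 2 parts of the rule counted under both. Genes given outside this rule are members of the fixed lists, shown as examples, or are said to have been chosen after their values were seen.

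Each result was recomputed with pseudocounts of 0.1 and 0.5 in place of 1, without the filter and with a mean of at least 5 TPM, with TMM factors and with quantile normalization, and without the intensity trend. Further alternatives were array weights, a replicate block, fits of only the 2 groups compared, an absolute log2 change of at least 1, and leaving out each library. The cut on the log2 change was applied to counts of called genes only. Array weights came from a fit that did not converge. They gave bzip59 white light 3 a weight of 6.64e-06 and so nearly left that library out. Added after the data were seen were a fit without the white-light libraries numbered 2, a fit of protein-coding genes, and removal of each library's trend with gene length. Planned count-based tests were not run because the table holds TPM and no counts.

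The pipeline was tested on simulated data with 100 changed genes per size among 19693. At a log2 change of 1 the fit recovered between 69% and 74% in the pairwise contrasts and 28% in the interaction. At a log2 change of 2 it recovered between 96% and 98%, and 85% in the interaction. False calls were between 1.7% and 6.2% of the genes called. Changed genes were drawn only from those with a mean log2 level equal to at least 5 TPM, and noise was independent between genes. Differences in scaling or gene length trend between libraries were not simulated. Recovery of lower genes is thus unknown, and the share of false calls may differ in the real libraries.

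The labels give no source that libraries with the same replicate number share, and the replicate block was run only as an alternative. An exploratory covariate built from ribosomal protein transcripts was looked at and not kept. Transcript isoforms were examined for bZIP59 only.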

Results

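Transcript levels were measured by RNA-seq in whole Arabidopsis seedlings of the wild type Col-0 and of bzip59, an insertion mutant of the transcription factor gene bZIP59. Seedlings grown for 7 days in continuous white light either stayed there or received 2 h of shade, given as a red to far-red ratio of 0.65. The 4 groups held 3 libraries each, 12 in all, and values are given as mean TPM ± SD with n = 3 unless stated. The depth behind the values is unknown, because TPM keeps no read counts, and between 18950 and 19689 genes reached 1 TPM in a library. Fold changes are log2 values of TPM + 1, which understate changes of low transcripts, and the median 95% confidence interval of a pairwise change was 0.41 wide on either side. The labels do not say whether the 3 libraries of a group came from separately grown seedlings, so every p-value measures only the spread between these samples. Strandedness was not stated, so values of overlapping and antisense genes are uncertain. Values of closely paralogous genes are uncertain as well, because reads may be shared between them.

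Several library properties varied along with the groups. Seed storage transcripts summed to 190, 56.1 and 31.7 TPM in the bzip59 white-light libraries and to 79.2, 10.1 and 2.39 TPM in the bzip59 shade libraries. The same transcripts summed to 9.57, 9.39 and 7.13 TPM in Col-0 white light and to 5.22, 3.87 and 2.62 TPM in Col-0 shade. Within all 4 groups these sums fell from library 1 to 2 to 3, an order that the unpaired tests do not use. Library 2 of bzip59 white light stood apart, with a TMM factor of 0.835 and a Spearman correlation of -0.53 between its deviation from the group means and gene length across genes. Libraries 1 of Col-0 shade and 2 of bzip59 shade also differed from the other libraries of their groups. Abscisic acid and dehydration genes summed to 1646 TPM in Col-0 shade 1, against 642 and 674 TPM, and to 1553 TPM in bzip59 shade 2, against 515 and 459 TPM. Light-harvesting genes summed to 42820 TPM there, against 67360 and 69360 TPM, and to 44630 TPM, against 64300 and 64160 TPM. In the same 2 libraries flavonoid genes summed to 531 and 520 TPM, against at most 265 TPM in the other shade libraries. The mean log2 level there was 3.99 and 3.86 for the sulfur list and 4.31 and 3.89 for the jasmonate list, against at most 3.22 and 3.54. The median change of all 19693 tested genes was -0.16 for bzip59 against Col-0 in white light, 0.11 for shade in bzip59 and 0.15 for the interaction. With TMM factors these medians were -0.01, -0.01 and 0.01, so changes in those 3 comparisons are read against the medians given. For shade in Col-0 and for genotype in shade the medians were -0.01 and -0.003.

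The level of bZIP59 itself (AT2G31370, listed as POSF21) was examined first, to ask how far the mutation lowered its transcript. In white light bZIP59 reached 20.6 ± 2.71 TPM in Col-0 and 4.15 ± 1.2 TPM in bzip59, or 20.2% of the wild-type level. In shade it reached 23.1 ± 3.23 TPM in Col-0 and 7.33 ± 1.1 TPM in bzip59, or 31.7%. Transcript 7 of the gene carried 11.8 ± 6.38 TPM in Col-0 white light and 0.13 ± 0.03 TPM in bzip59 white light, and was listed at 0 in bzip59 shade. Transcript 1 was at 0.73 ± 1.27 TPM in Col-0 white light and 2.3 ± 1.36 TPM in bzip59 white light, and at 1.72 ± 2.42 and 4.78 ± 0.76 TPM in shade. Shade left bZIP59 without a called change in Col-0 (log2 0.16, limma adjusted p = 0.675), and the residual transcript rose by 0.71 in bzip59 (limma adjusted p = 0.0309, range over alternatives 0.0113 to 0.132), while the interaction of 0.55 failed the test (limma adjusted p = 0.618). The rise in bzip59 lost its call without bzip59 shade 1 (limma adjusted p = 0.109), bzip59 shade 3 (0.132) or bzip59 white light 3 (0.115), and with TMM factors (0.0836), quantile normalization (0.105), the gene length trend removed (0.124), array weights (0.0856) and the 2 groups alone (0.099). The genotype difference was log2 -2.09 in white light (SE 0.18, limma adjusted p = 0.00128, range over alternatives 0.000538 to 0.262) and -1.53 in shade (SE 0.18, limma adjusted p = 0.00967, range over alternatives 3.63e-05 to 0.105). The genotype call in shade ended without Col-0 shade 1 (limma adjusted p = 0.0507), Col-0 shade 2 (0.0637), bzip59 shade 1 (0.0624) or bzip59 shade 2 (0.105), and no value of bzip59 overlapped Col-0 in either light.

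**Figure D1:**
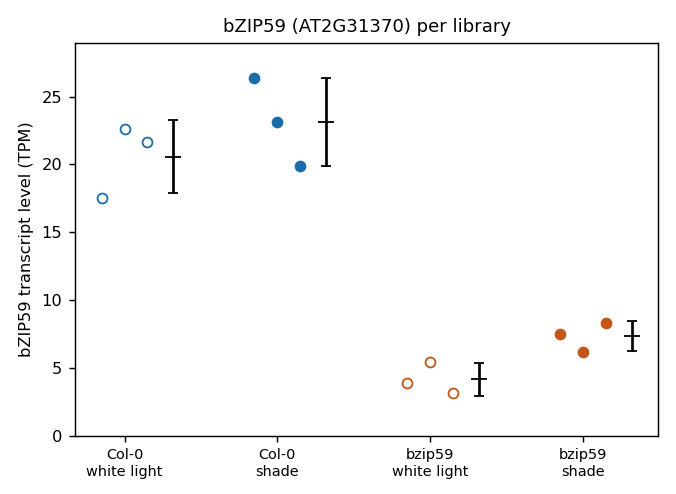
bZIP59 level in TPM (vertical axis) in the 12 libraries by group, with points as libraries (open circles white light, filled circles shade) and black bars as mean ± SD, n = 3. The bzip59 libraries sit between 3.12 and 8.32 TPM and the Col-0 libraries between 17.5 and 26.3 TPM.

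Shade against white light in Col-0 asked which transcripts responded to 2 h of shade in the wild type. The auxin-response repressor gene IAA29 (AT4G32280) rose from 1.17 ± 0.15 TPM to 85.3, 118 and 113 TPM in the 3 shade libraries (log2 5.60, SE 0.17, limma adjusted p = 1.6e-08). FLP1 (AT4G31380), named for its likeness to a flowering-promoting factor, rose from 0.6 ± 0.52 to 89.6 ± 4.19 TPM, and the transcription factor gene BHLH87 (AT3G21330) from 1.65 ± 0.42 to 67.5 ± 11.5 TPM. BIC2 (AT3G44450), an inhibitor of cryptochrome blue-light receptors, fell from 49.3 ± 2.09 to 5.32 ± 1.13 TPM, and PIF7 (AT5G61270), a transcription factor gene of shade signalling, fell from 27.8 ± 2.76 to 5.84 ± 0.32 TPM. LEA2 (AT1G02820) fell from 87 ± 28.7 to 4.89 ± 1.15 TPM. The leucine-rich repeat gene AT4G16880 measured 13.4, 14.3 and 12 TPM in white light and was listed at 0 in all 3 Col-0 shade libraries. The small nuclear RNA U5.5 (AT1G05853) was listed at 0 in white light and at 42.5, 147 and 209 TPM in shade, although libraries were made from poly(A) RNA.

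Early shade genes rose as a group in Col-0. Of the 24 genes of that list 21 rose and 1 fell over all genes, and 22 rose and 1 fell adjusted over the list alone. ATHB2, a homeodomain gene used as a shade marker, went from 7.22 ± 1.59 to 95.4 ± 3.72 TPM, and PIL1 rose by log2 3.96. HFR1, a brake on shade growth, rose by log2 2.71. BBX25, a B-box gene at the locus next to bZIP59, was the gene that fell, from 48.9 ± 9.15 to 27.4 ± 5.7 TPM. Camera from limma gave the list an adjusted p of 1.26e-28, and adjusted p = 0.00524 with an estimated correlation. Auxin-response genes rose in 28 of 30 cases and fell in 1, with the same counts adjusted over the list alone (median log2 1.70). IAA19 rose from 5.45 ± 1.17 to 136 ± 22.8 TPM, and the growth-promoting SAUR22 went from 1.85 ± 0.32 to 31.1 ± 2.67 TPM. The camera test from limma gave them an adjusted p of 7.86e-36, and adjusted p = 0.00797 with an estimated correlation.

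Of 13 genes of auxin synthesis and transport 7 rose in Col-0 and none fell, against 7 rises and 2 falls adjusted over the list alone. YUC2, YUC5, YUC8 and YUC9 rose and also stand on the early shade list, so they count in both. Other lists overlap too. IAA19 and IAA29 of auxin response, XTH15, PRE1, GA20OX1 and CKX5 also stand on the early shade list. XTH22 stands on both the XTH list and the touch, wound and cold list. Results of overlapping lists are thus not separate. The auxin-synthesis gene YUC8 rose from 1.86 ± 0.37 to 28.3 ± 3.38 TPM, and the auxin carrier gene PIN3 from 45.7 ± 6.78 to 107 ± 14.3 TPM (camera from limma, adjusted p = 2.2e-06, and adjusted p = 0.0959 with an estimated correlation). Ethylene genes rose in 7 of 12 cases and in 10 adjusted over the list alone. Among them the synthesis gene ACS8 rose by log2 4.17 and EBF2, which promotes turnover of ethylene transcription factors, by log2 1.68 (camera from limma, adjusted p = 6.1e-11, and adjusted p = 0.0207 with an estimated correlation). Brassinosteroid genes rose in 7 of 14 cases and fell in 1, or 8 and 3 adjusted over the list alone, with BEE1 going from 7 ± 1.46 to 69 ± 17.8 TPM (camera from limma, adjusted p = 0.000633, and adjusted p = 0.23 with an estimated correlation). Gibberellin genes rose in 4 of 15 cases and fell in 1, or 5 and 1 adjusted over the list alone. GA20OX2 of gibberellin synthesis rose by log2 2.46 and GA2OX6 of gibberellin breakdown by log2 2.37 (camera from limma, adjusted p = 0.014, and adjusted p = 0.202 with an estimated correlation).

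Cell wall and growth genes of the XTH list, which remodel xyloglucan, rose in 6 of 12 cases in Col-0 and in 10 adjusted over the list alone. XTH22 rose by log2 2.72 and XTH33 by log2 3.26 (camera from limma, adjusted p = 6.1e-11, and adjusted p = 0.0814 with an estimated correlation). Of the 5 PRE family genes, small growth-promoting bHLH proteins, 3 rose on both adjustments, and PRE6 rose by log2 2.49 (camera from limma, adjusted p = 0.00922, and adjusted p = 0.0814 with an estimated correlation). Touch, wound and cold genes rose in 3 of 12 cases, against 5 rises and 1 fall adjusted over the list alone. The calmodulin-like gene TCH3 rose by log2 2.33 (camera from limma, adjusted p = 0.000139, and adjusted p = 0.23 with an estimated correlation). Within bZIP group I, which includes bZIP59, 2 of 7 genes rose on both adjustments, among them BZIP52 by log2 0.64 (camera from limma, adjusted p = 0.0202, and adjusted p = 0.106 with an estimated correlation).

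Clock and sulfur genes went down in Col-0 shade. Of 17 clock genes 1 rose and 10 fell, or 1 and 11 adjusted over the list alone. ELF4, an evening clock component, fell from 120 ± 5.91 to 48.2 ± 0.74 TPM, and RVE1 from 40.7 ± 1.76 to 15.6 ± 6.07 TPM (camera from limma, adjusted p = 5.8e-06, and adjusted p = 0.0121 with an estimated correlation). Sulfur-response genes fell in 7 of 8 cases on both adjustments. APR3 of sulfate reduction fell from 150 ± 38.2 to 28.7 ± 14.3 TPM, and the sulfur-starvation marker LSU1 fell from 27.9 ± 1.66 to 6.05 ± 2.26 TPM (camera from limma, adjusted p = 9.66e-07, and adjusted p = 0.17 with an estimated correlation). Light-signalling genes fell in 9 of 19 cases and rose in 4 on both adjustments. The photoreceptor gene PHYA rose from 21.3 ± 4.81 to 66.9 ± 16.4 TPM, and HYH, a light-signalling bZIP gene, fell by log2 -1.48 (camera from limma, adjusted p = 0.0246, and adjusted p = 0.498 with an estimated correlation). Flavonoid genes fell in 2 of 14 cases and in 6 adjusted over the list alone, with the regulator MYB12 at log2 -1.04 (camera from limma, adjusted p = 0.0246, and adjusted p = 0.581 with an estimated correlation). For light harvesting 0 of 18 genes passed on either adjustment by limma, the median was log2 0.23, and camera from limma gave an adjusted p of 0.014, and adjusted p = 0.581 with an estimated correlation. The light-signalling call ended without Col-0 white light 1 (camera adjusted p = 0.0794) and the flavonoid call without Col-0 shade 2 (0.0662). The light-harvesting call ended without Col-0 white light 2 (camera adjusted p = 0.201), Col-0 shade 2 (0.178) or Col-0 shade 3 (0.142), and with quantile normalization (0.0974). Without both white-light libraries numbered 2 the camera adjusted p was 0.22 for light harvesting and 0.0747 for flavonoids. Col-0 shade 1 stood apart from the other shade libraries in the sulfur, flavonoid and light-harvesting lists, as given above.

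Over all genes, limma called 1954 in Col-0, of which 674 rose and 1280 fell, and 767 had an absolute log2 change of at least 1. The groups did not overlap for 1946 of the 1954 genes and for 27.9% of all tested genes, where chance gives 10%. Without Col-0 shade 2, Col-0 shade 3 or Col-0 white light 2 the count was 1187, 976 or 1257. AT2G01021 (0, 0 and 90.2 TPM in white light, 531, 722 and 537 TPM in shade), AT1G05917, U6.5 (AT4G08755) and AT3G04165 were among the 8 largest rises, and their calls ended in 8, 6, 6 and 5 of the 12 fits with 1 library left out, with highest limma adjusted p of 0.161, 0.122, 0.0725 and 0.121.

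Shade against white light in bzip59 asked which transcripts responded in the mutant. The 3 genes with the largest rises were FLP1, IAA29 and BHLH87, which were also among the 8 largest rises in Col-0. FLP1 rose from 0.27 ± 0.28 to 100 ± 2.92 TPM, and BHLH87 from 1.49 ± 0.33 to 67.6 ± 9.34 TPM. IAA29 rose from 0.87 ± 0.25 to 127 ± 21 TPM (log2 6.09, SE 0.17, limma adjusted p = 6.24e-09). GH3.3, which conjugates auxin to amino acids, rose from 3.75 ± 1.33 to 94.9 ± 8.06 TPM, and the sulfotransferase gene ST2A from 1.37 ± 0.48 to 49.7 ± 10.6 TPM. BIC2 fell from 59.7 ± 14 to 4.77 ± 1.32 TPM, LEA2 from 54.9 ± 12.6 to 6.86 ± 0.68 TPM and PIF7 from 18.9 ± 2.28 to 7.85 ± 1.18 TPM. The cell-cycle inhibitor gene SMR5 (AT1G07500) measured 6.39, 9.47 and 5.95 TPM in white light and was listed at 0 in all 3 shade libraries. AT4G16880 was also listed at 0 there, from 9.49, 7.87 and 6.33 TPM in white light.

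Early shade genes rose in 20 of 24 cases in bzip59, and in 22 adjusted over the list alone, with a median of log2 1.75. ATHB2 went from 6.17 ± 0.56 to 93.9 ± 17.5 TPM, and HFR1 rose by log2 3.24 (camera from limma, adjusted p = 6.16e-25, and adjusted p = 0.00846 with an estimated correlation). Auxin-response genes rose in 26 of 30 cases and fell in 1, or 27 and 1 adjusted over the list alone, and IAA19 went from 5.35 ± 1.16 to 122 ± 26.2 TPM (camera from limma, adjusted p = 4.34e-25, and adjusted p = 0.0247 with an estimated correlation). Ethylene genes rose in 9 of 12 cases, or 10 adjusted over the list alone, with ACS8 up by log2 4.07 (camera from limma, adjusted p = 6.9e-09, and adjusted p = 0.0369 with an estimated correlation). Of the 7 bZIP group I genes 4 rose, or 7 adjusted over the list alone, among them bZIP59 itself and BZIP69 by log2 0.95 (camera from limma, adjusted p = 0.000335, and adjusted p = 0.0369 with an estimated correlation). These 4 lists were those whose calls held with an estimated correlation in bzip59. In Col-0 the lists that held were early shade, auxin response, ethylene and clock.

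XTH genes rose in 8 of 12 cases in bzip59, or 9 adjusted over the list alone, with XTH33 up by log2 3.37 (camera from limma, adjusted p = 3.74e-07, and adjusted p = 0.18 with an estimated correlation). Auxin synthesis and transport genes rose in 6 of 13 cases and fell in 1, or 9 and 1 adjusted over the list alone, with YUC8 up by log2 3.56 (camera from limma, adjusted p = 3.74e-05, and adjusted p = 0.18 with an estimated correlation). Brassinosteroid genes rose in 8 of 14 cases, or 9 with 1 fall adjusted over the list alone, and the synthesis gene CPD went from 46.8 to 124 TPM (camera from limma, adjusted p = 9.6e-05, and adjusted p = 0.21 with an estimated correlation). Touch, wound and cold genes rose in 4 of 12 cases, or 5 adjusted over the list alone, with TCH3 up from 43.9 ± 3.04 to 211 ± 61.9 TPM (camera from limma, adjusted p = 0.000941, and adjusted p = 0.299 with an estimated correlation). Gibberellin genes rose in 5 of 15 cases and fell in 1, or 7 and 1 adjusted over the list alone, with the DELLA repressor gene GAI up by log2 1.37 (camera from limma, adjusted p = 0.0223, and adjusted p = 0.21 with an estimated correlation). The gibberellin call ended without bzip59 white light 1 (camera adjusted p = 0.079) and without the filter on low values (0.0542).

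Light-harvesting genes rose in 5 of 18 cases in bzip59 shade, or 11 with 1 fall adjusted over the list alone. LHCB4.2, an antenna protein gene of photosystem II, went from 822 ± 86.6 to 1770.5 ± 353 TPM (camera from limma, adjusted p = 0.000285, and adjusted p = 0.44 with an estimated correlation). The difference of the list's shade effect from that in Col-0 did not pass (camera from limma, adjusted p = 0.211), and passed without Col-0 white light 2 (0.00459), Col-0 shade 2 (0.0203), Col-0 shade 3 (0.0137) or bzip59 shade 2 (0.00606). It also passed with the gene length trend removed (camera adjusted p = 0.0165), with quantile normalization (0.000223) and without both white-light libraries numbered 2 (0.00804). Sulfur-response genes fell in 6 of 8 cases, or 7 adjusted over the list alone, with LSU1 down from 29.5 to 5.98 TPM (camera from limma, adjusted p = 2.48e-07, and adjusted p = 0.18 with an estimated correlation). Flavonoid genes fell in 3 of 14 cases on both adjustments, and MYB12 was at log2 -0.96 (camera from limma, adjusted p = 9.6e-05, and adjusted p = 0.299 with an estimated correlation). Seed storage genes fell in 1 of 7 cases, or 3 adjusted over the list alone, and SESA3 went from 6.91 ± 5.89 to 0.58 ± 0.43 TPM (camera from limma, adjusted p = 8.95e-05, and adjusted p = 0.21 with an estimated correlation). The SESA3 call ended without bzip59 shade 1 (limma adjusted p = 0.0538), bzip59 shade 3 (0.0903) or bzip59 white light 3 (0.0663). Iron-response genes passed in 0 of 14 cases by limma on either adjustment, at a median of log2 -0.14 (camera from limma, adjusted p = 0.0223, and adjusted p = 0.304 with an estimated correlation). The iron call ended without bzip59 white light 3 (camera adjusted p = 0.0629) or bzip59 shade 2 (0.0716), and with the gene length trend removed (0.0719). In the light-harvesting, sulfur and flavonoid lists bzip59 shade 2 stood apart, as given above. Clock genes rose in 1 of 17 cases and fell in 2, or 4 and 3 adjusted over the list alone, where ELF4 went from 115 to 47.5 TPM (camera from limma, adjusted p = 0.436). The clock median was log2 -0.05 and the mean 0.01, and the light-signalling median of 0.07 turned to -0.06 with TMM factors.

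Limma called 2007 genes in bzip59, of which 1278 rose and 729 fell, or 675 with an absolute log2 change of at least 1. The groups did not overlap for 2004 of the 2007 and for 32% of all tested genes, where chance gives 10%. The split was 887 up and 1158 down with TMM factors, 955 and 1077 with quantile normalization and 1182 and 1122 with the length trend removed. Without bzip59 shade 1, bzip59 shade 3, bzip59 white light 1 or bzip59 white light 3 the count was 871, 890, 3305 or 1133.

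**Figure D2:**
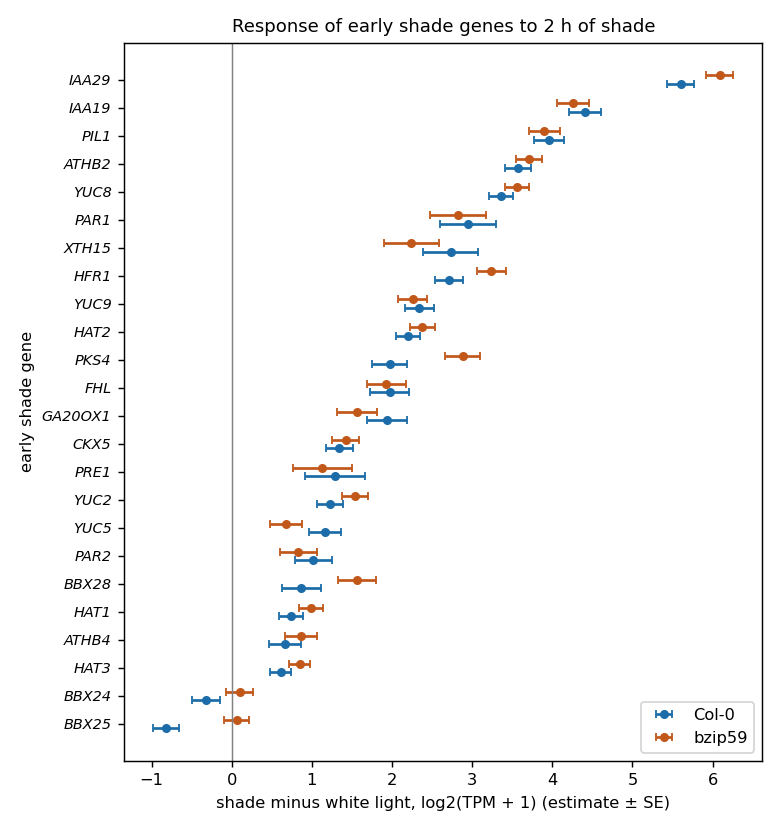
Shade effect on 24 early shade genes in Col-0 and bzip59 in log2(TPM + 1), with points as limma estimates ± SE. ATHB2 was at 3.57 in Col-0 and 3.71 in bzip59, and BBX25 was at -0.82 and 0.06.

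Both shade responses were compared to ask how alike they were. Their fold changes share no library. The calls came from a single fit, in which each gene's variance was estimated over all libraries. Calls in the genotypes are therefore not independent, and the overlaps expected from independent calls do not allow for this shared variance. Shade raised 520 genes in both genotypes, where 43.7 would be expected from independent calls, and lowered 522 in both, where 47.4 would be expected. None was called in opposite directions. ATHB2, PIL1, IAA29, IAA19, YUC8 and BIC2 were among the shared calls. The log2 changes had a Pearson correlation of 0.633 and a Spearman correlation of 0.535 across the 19693 genes, which are not independent replicates.

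Bzip59 against Col-0 in white light asked which transcripts differed before shade. AT1G75945, an uncharacterised gene, was at 0.3 ± 0.27 TPM in Col-0 and 39.9 ± 8.47 TPM in bzip59 (log2 4.97, SE 0.18, limma adjusted p = 1.18e-07, range over alternatives 1.65e-08 to 0.00699). AT3G57940, annotated as an RNA cytidine acetyltransferase, was at 0.15 ± 0.03 and 3.7 ± 0.78 TPM (log2 2.02, limma adjusted p = 0.00579). QQS (AT3G30720), an orphan gene that affects starch, was lower in bzip59, at 3.59 ± 1.37 against 16.3 ± 2.22 TPM (log2 -1.95, limma adjusted p = 0.00612). ROC4 (AT3G62030), a chloroplast cyclophilin, was at 394 ± 25.9 against 812 ± 107 TPM (log2 -1.04, limma adjusted p = 0.0395). A paralog of AT3G57940, AT1G10490, was at 7.2 TPM in Col-0 and 5.18 TPM in bzip59. These 4 genes and bZIP59 were the 5 called of 19693, while 3047 genes had an unadjusted p under 0.05. All 5 had groups that did not overlap, as did 18.4% of tested genes, where chance gives 10%.

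In single libraries left out, the AT3G57940 call ended without bzip59 white light 3 (limma adjusted p = 0.0544). ROC4 lost its call without Col-0 white light 1 (limma adjusted p = 0.103), Col-0 white light 2 (0.106), Col-0 shade 2 (0.0512), Col-0 shade 3 (0.106), bzip59 white light 1 (0.0774), 2 (0.115) or 3 (0.11), or bzip59 shade 1 (0.063), 2 (0.0595) or 3 (0.0838). In the 2 groups alone the calls of AT3G57940 (limma adjusted p = 0.0718), QQS (0.273) and ROC4 (0.363) ended, and only that of AT1G75945 held in every alternative. AT3G57940 also lost its call with array weights (limma adjusted p = 0.099), which gave bzip59 white light 3 almost no weight. QQS lost its call without both white-light libraries numbered 2 (limma adjusted p = 0.0918). The same fit ended the ROC4 call (limma adjusted p = 0.193), as did no filter (0.0582), TMM factors (0.191), no intensity trend (0.0663), array weights (0.104) and the gene length trend removed (0.144). The count of called genes was 11 without Col-0 white light 2, 14 without Col-0 white light 3, 8 without bzip59 shade 2, 11 without bzip59 white light 1 and 3 without bzip59 white light 3.

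**Figure D3:**
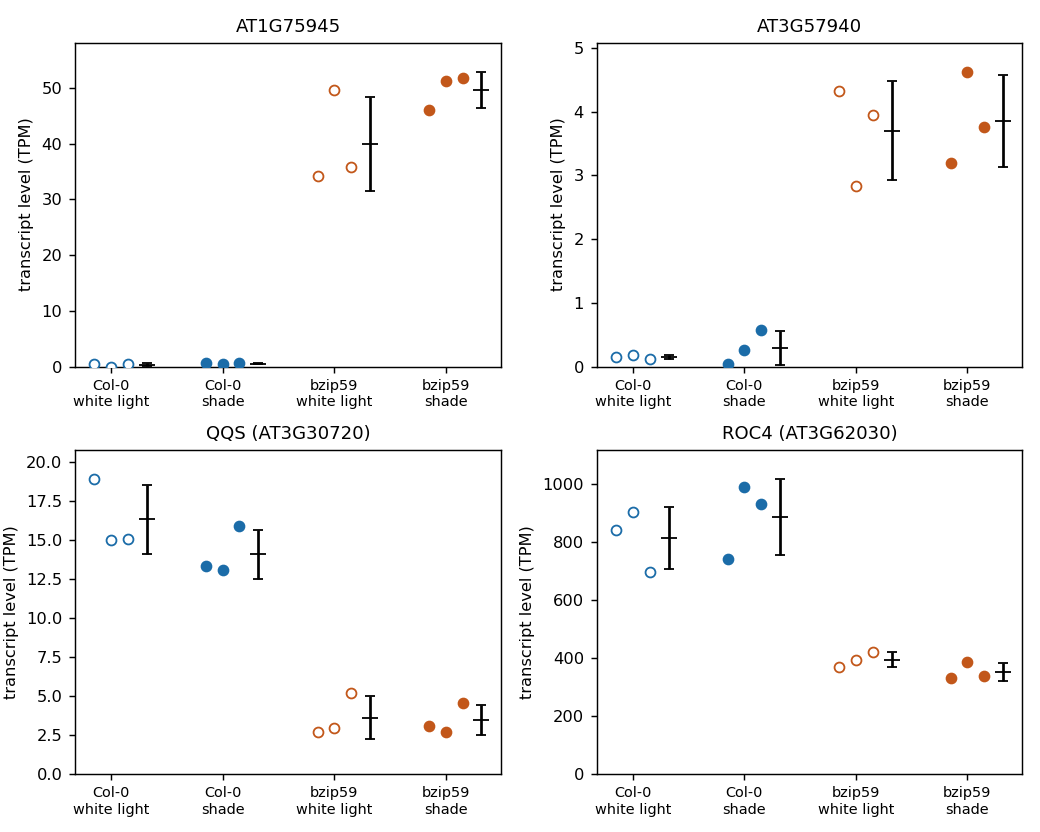
Levels of AT1G75945, AT3G57940, QQS and ROC4 in TPM (vertical axes) in the 12 libraries by group, with points as libraries (open circles white light, filled circles shade) and black bars as mean ± SD, n = 3. AT1G75945 was at 0.3 and 0.53 TPM on average in Col-0 and at 39.9 and 49.7 TPM in bzip59.

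Clock genes were lower as a group in bzip59 white light. All 17 had a negative change, with a median of log2 -0.55 against -0.16 for all genes, 0 of 17 passed limma over all genes, and 12 fell adjusted over the list alone. The morning gene CCA1 was at 25.1 ± 6.13 TPM in bzip59 and 51.6 ± 4.01 TPM in Col-0, and its partner LNK2 at 24.6 ± 3.5 and 56.6 ± 9.93 TPM. Camera from limma gave an adjusted p of 2.57e-05, and adjusted p = 0.0385 with an estimated correlation, the only list of this comparison to hold. Light-signalling genes were negative in 19 of 19 cases at a median of log2 -0.32, and 3 fell adjusted over the list alone. PIF5, a growth-promoting bHLH gene, was at 12.7 ± 1.23 TPM in bzip59 and 25.4 ± 2.61 TPM in Col-0 (log2 -0.95, limma adjusted p = 0.0914). That list had a camera adjusted p of 0.00233 from limma, and adjusted p = 0.532 with an estimated correlation.

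Seed storage genes were higher in bzip59 white light in 7 of 7 cases at a median of log2 2.54, with 0 called over all genes by limma and 6 adjusted over the list alone. The cruciferin gene CRA1 measured 66.7, 19.7 and 7.55 TPM in bzip59 and 2.91, 1.55 and 1.45 TPM in Col-0 (camera from limma, adjusted p = 1.9e-11, and adjusted p = 0.101 with an estimated correlation). The bZIP group I list passed downward with 1 of 7 genes called on both adjustments, the mutated bZIP59 itself, so the genotype alone lowers part of this list (camera from limma, adjusted p = 0.0161, and adjusted p = 0.127 with an estimated correlation). Expansins at a median of log2 0.12 and auxin-response genes at 0.04 passed upward with 0 genes called by limma on either adjustment (camera from limma, adjusted p = 0.00871 for each, and adjusted p = 0.101 and 0.856 with an estimated correlation). The auxin call ended without Col-0 white light 2 (camera adjusted p = 0.133) or bzip59 white light 2 (0.351), the expansin call without Col-0 white light 3 (0.0954) or bzip59 white light 2 (0.0566), and the bZIP call without bzip59 white light 1 (0.0769). With TMM factors the auxin and bZIP calls ended (camera adjusted p = 0.0689 for each), as they did with quantile normalization (0.107 for each) and with the gene length trend removed (0.509 and 0.0606). The auxin call also ended without both white-light libraries numbered 2 (camera adjusted p = 0.907), and the expansin call with quantile normalization (0.0832). Light-harvesting genes, at a median of log2 -0.40, did not pass (camera from limma, adjusted p = 0.0805) and passed without Col-0 white light 2 (0.000554) or Col-0 shade 1 (0.0216). They also passed with the gene length trend removed (median log2 -0.38, camera adjusted p = 0.00353), with quantile normalization (1.76e-06), without the filter (0.0354), in the 2 groups alone (0.0126) and without both white-light libraries numbered 2 (0.000793). The log2 changes of this comparison had a Spearman correlation of -0.391 with gene length across genes.

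Bzip59 against Col-0 in shade addressed the effect of bZIP59 during shade. AT1G75945 was at 0.53 ± 0.06 TPM in Col-0 and 49.7 ± 3.18 TPM in bzip59 (log2 5.05, SE 0.18, limma adjusted p = 1.01e-07, range over alternatives 1.32e-11 to 0.00119). AT3G57940 was at 0.29 ± 0.27 and 3.86 ± 0.72 TPM (log2 1.92, limma adjusted p = 0.00727), and QQS was lower at 3.44 ± 0.97 against 14.1 ± 1.56 TPM (log2 -1.78, limma adjusted p = 0.00967). ROC4 was at 350.3 ± 30.5 against 886 ± 130 TPM (log2 -1.33, limma adjusted p = 0.00551). The long noncoding RNA AT4G06665 measured 20.1, 7.33 and 23.8 TPM in bzip59 and was listed at 0 in the Col-0 shade libraries (limma adjusted p = 0.00551). The noncoding RNA AT1G67105 was at 7.81 ± 0.06 against 2.67 ± 0.66 TPM (log2 1.28, limma adjusted p = 0.0219), and AT1G27565 was lower at 0.11 ± 0.1 against 5.49 ± 0.99 TPM (log2 -2.54, limma adjusted p = 0.00967). With bZIP59 these were the 8 called genes, while 533 genes had an unadjusted p under 0.05. All 8 had groups that did not overlap, as did 9.8% of tested genes, where chance gives 10%. With TMM factors 3 genes were higher and 4 lower, and with the length trend removed 4 and 2.

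QQS lost its shade call without Col-0 shade 2 (limma adjusted p = 0.0503), Col-0 shade 3 (0.0876), bzip59 shade 1 (0.0701) or bzip59 shade 2 (0.105). AT1G27565 lost it without Col-0 shade 2 (limma adjusted p = 0.0719), Col-0 shade 3 (0.0876), bzip59 shade 1 (0.0624), bzip59 shade 2 (0.072) or bzip59 shade 3 (0.0826). AT1G67105 lost it without Col-0 white light 1 (limma adjusted p = 0.055) or 2 (0.0507), Col-0 shade 1 (0.0632) or 3 (0.102), bzip59 white light 3 (0.0595), or bzip59 shade 1 (0.133), 2 (0.167) or 3 (0.123). In the 2 groups alone AT4G06665, QQS and ROC4 (limma adjusted p = 0.0971 for each), AT3G57940 (0.153) and AT1G67105 (0.255) lost their calls, and only AT1G75945 kept its call in every alternative. QQS also lost it without both white-light libraries numbered 2 (limma adjusted p = 0.0542) and with the gene length trend removed (0.051). AT1G67105 lost it in the first of these fits (limma adjusted p = 0.0641), without the filter (0.0556), with a mean of at least 5 TPM (0.0578), with TMM factors (0.159) and with quantile normalization (0.292). Without bzip59 shade 1 limma called 5 genes.

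Early shade genes had a median of log2 -0.07 with 0 of 24 called by limma on either adjustment (camera from limma, adjusted p = 0.943), and clock genes a median of 0.14 with 0 of 17 called on either adjustment (camera from limma, adjusted p = 0.341). Without bzip59 shade 2 both lists passed (camera adjusted p = 0.0476 for each), the early shade list on the side opposite to its test with all libraries, and the number of passing lists went from 1 to 12 as each library was left out. Light-signalling genes passed at a median of log2 0.16 and seed storage genes at 0.62, with 0 genes called by limma on either adjustment (camera from limma, adjusted p = 0.0291 for each, and adjusted p = 0.761 for each with an estimated correlation). Expansins at a median of log2 0.24, with 1 gene higher adjusted over the list alone, and nitrate and phosphate genes at 0.18 also passed (camera from limma, adjusted p = 0.0339 for each, and adjusted p = 0.554 and 0.761 with an estimated correlation). The light-signalling call ended without Col-0 shade 1 (camera adjusted p = 0.122), bzip59 shade 1 (0.108) or bzip59 shade 3 (0.111), and the seed storage call without Col-0 shade 1 (0.165) or bzip59 shade 1 (0.636). The expansin call ended without Col-0 white light 3 (camera adjusted p = 0.0567), Col-0 shade 1 (0.288), bzip59 white light 2 (0.0589) or 3 (0.0555), or bzip59 shade 3 (0.116). It also ended with the gene length trend removed (camera adjusted p = 0.0974), TMM factors (0.14), quantile normalization (0.0859), the 2 groups alone (0.157) and both white-light libraries numbered 2 left out (0.0774). The nitrate and phosphate call ended without Col-0 white light 3 (camera adjusted p = 0.0502), Col-0 shade 2 (0.0749), Col-0 shade 3 (0.124) or bzip59 shade 3 (0.157), and without the filter (0.182).

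The interaction asked whether the shade response itself differed between the genotypes. For ATHB2 the difference was log2 0.14 (95% confidence interval -0.37 to 0.65), for PIL1 -0.07 (-0.65 to 0.51), for IAA19 -0.14 (-0.77 to 0.49) and for YUC8 0.20 (-0.26 to 0.66). BBX25 fell in Col-0 by 0.82 on the log2 scale (limma adjusted p = 0.00677) and was at 0.06 in bzip59, with 39.6 ± 1.36 TPM in white light and 41.3 ± 1.87 TPM in shade. Its interaction was 0.88 (0.39 to 1.36, limma adjusted p = 0.536). PKS4, a phytochrome signalling gene, had an interaction of 0.90 (0.21 to 1.6, limma adjusted p = 0.586). The 4 genes with the smallest p failed the correction, namely AT4G06665 (log2 4.46, SE 0.59, limma adjusted p = 0.155), AT4G31354 (1.91, SE 0.31, adjusted p = 0.417), the lipid-transport family gene AT1G55960 (1.51, SE 0.25, adjusted p = 0.417) and AT1G34630 (0.76, SE 0.14, adjusted p = 0.536). AT1G55960 went from 186 ± 26 to 29.4 ± 5.36 TPM in Col-0 and from 96.4 ± 8.97 to 44.2 ± 9.05 TPM in bzip59.

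Limma called 0 genes for the interaction, with 1577 at an unadjusted p under 0.05. Without Col-0 shade 1 it called 2 genes, without Col-0 white light 3 2, without bzip59 shade 2 4, without bzip59 white light 1 1, and without bzip59 white light 2 1. Without bzip59 shade 2 AT4G06665 had a limma adjusted p of 0.00886, the lowest over its alternatives, whose highest was 0.673.

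Clock and light-signalling genes had more positive interactions than other genes. The clock list was positive in 16 of 17 cases at a median of log2 0.49, with 0 called over all genes by limma and 8 adjusted over the list alone (camera from limma, adjusted p = 4.5e-05, and adjusted p = 0.0448 with an estimated correlation). CCA1 went from 51.6 ± 4.01 to 29.4 ± 3.94 TPM in Col-0 and from 25.1 ± 6.13 to 39.4 ± 7.95 TPM in bzip59. The light-signalling list was positive in 18 of 19 cases at a median of 0.48, with 0 called by limma over all genes and 5 adjusted over the list alone (camera from limma, adjusted p = 4.5e-05, and adjusted p = 0.451 with an estimated correlation). PIF5 was at 25.4 ± 2.61 and 24.2 ± 2.68 TPM in Col-0 and at 12.7 ± 1.23 and 23.5 ± 3.85 TPM in bzip59. Seed storage genes were negative in 7 of 7 cases at a median of -1.57, with 0 called by limma on either adjustment (camera from limma, adjusted p = 4.5e-05, and adjusted p = 0.451 with an estimated correlation). Their mean log2 level in Col-0 was 0.764 in white light and 0.509 in shade, near the floor, where log2(TPM + 1) understates a fall. Summed over the 7 genes, TPM went from 8.49 ± 1.5 to 3.69 ± 1.09 in Col-0 and from 90.7 ± 85.7 to 30 ± 41.8 in bzip59. The interaction thus does not show a fall confined to bzip59. With the gene length trend removed the median was log2 0.20 for the clock, 0.16 for light signalling and -1.44 for seed storage (camera from limma, adjusted p = 0.000837, 0.000837 and 0.00641), where the median of all genes went from 0.15 to 0.01. Exact permutation of genotype within light over 400 relabelings gave p = 0.02 for the clock mean, 0.01 for light signalling and 0.37 for seed storage, or 0.29, 0.29 and 0.97 adjusted over the 29 lists. The lowest p this permutation can give is 0.005, or 0.145 adjusted over the 29 lists when only 1 list reaches it. Its adjusted values thus do not decide a single list. The permutation is exact only if genotype had no effect in either light, so a plain genotype difference also alters its p-values.

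**Figure D4:**
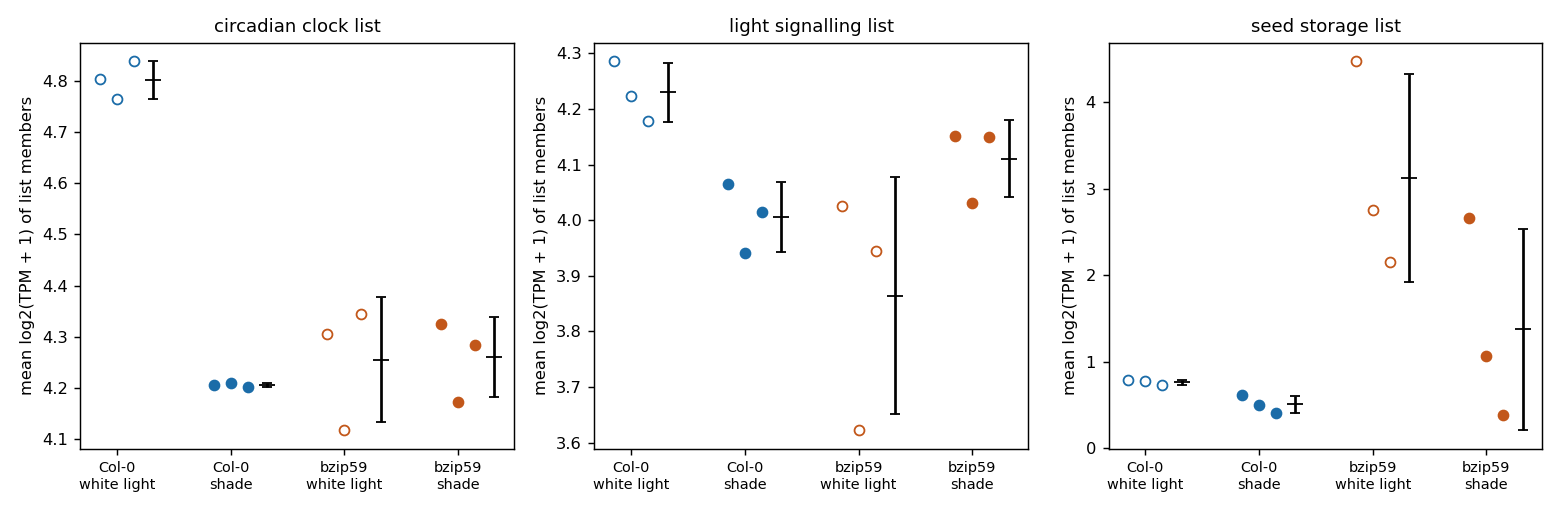
Mean log2(TPM + 1) of the clock, light-signalling and seed storage lists (vertical axes) in the 12 libraries by group, with points as libraries (open circles white light, filled circles shade) and black bars as mean ± SD, n = 3. In white light the clock mean was 4.80 ± 0.04 in Col-0 and 4.26 ± 0.12 in bzip59.

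Other lists passed camera from limma in neither shade comparison. Abscisic acid and dehydration genes had 4 falls among 18 in Col-0 (1 rise and 6 falls adjusted over the list alone), a median of log2 0.04, a mean of -0.04 and an adjusted p of 0.433, and 2 rises in bzip59, with a positive mean of 0.02 and a downward test (adjusted p = 0.436). Cytokinin genes had 2 rises and 1 fall among 12 in Col-0 (adjusted p = 0.405) and 2 rises and 2 falls in bzip59 (0.113), with CKX5 of cytokinin breakdown up by log2 1.34 and 1.42. Jasmonate genes had 2 rises and 4 falls among 21 in Col-0 (adjusted p = 0.405), and 2 and 2 in bzip59 (0.114), with the repressor gene JAZ9 at log2 -0.91 in both. The jasmonate list passed without Col-0 shade 1 (adjusted p = 0.021 in Col-0 and 0.0497 in bzip59) or bzip59 shade 2 (0.0424 in bzip59), the 2 libraries that stood apart in the jasmonate and abscisic acid lists, and the cytokinin list passed in bzip59 with a mean of at least 5 TPM (0.0176). Salicylate and immunity genes had 1 rise and 1 fall among 8 in each genotype (adjusted p = 0.789 and 0.993), with PAD4 at log2 -0.61 in both. Expansins had 1 rise and 2 falls among 8 in Col-0 (adjusted p = 0.22) and 1 fall in bzip59 (0.0843), EXPA5 at log2 -1.26, and passed in bzip59 without bzip59 white light 1 (0.0465) or bzip59 shade 3 (0.0437). Nitrate and phosphate genes had 1 fall among 8 in Col-0, SPX1 at log2 -1.61 (adjusted p = 0.769), and 3 rises and 1 fall in bzip59 (0.993), where the nitrate reductase gene NIA1 rose by log2 1.51.

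In Col-0 iron genes had 2 falls among 14 (3 adjusted over the list alone, camera from limma, adjusted p = 0.152) and passed without Col-0 shade 1 (0.0171). PRE genes in bzip59 had 1 rise among 5 (3 adjusted over the list alone, adjusted p = 0.22), and light-signalling genes 6 rises and 3 falls among 19 (adjusted p = 0.964). Heat shock genes had 0 calls among 6 by limma in either genotype (adjusted p = 0.789 and 0.964), and the 3 tested LBD genes had 0 (0.152 and 0.36). Dividing-cell markers had 0 calls among 5 (adjusted p = 0.921 and 0.993), and root-hair markers 0 among 6 (0.111 and 0.964), passing in Col-0 without white light 1 (0.0479) or white light 3 (0.0189). Green-tissue markers had 1 fall among 8 in Col-0 (adjusted p = 0.541) and 1 rise and 1 fall in bzip59 (0.915). Root markers had 0 calls among 7 in Col-0 (1 adjusted over the list alone, adjusted p = 0.152) and 1 rise in bzip59 (0.775). Seed storage genes, which lay near the floor in Col-0, had 0 calls among 7 there (adjusted p = 0.769). The median, mean and test differed in sign for heat shock in bzip59 (median log2 0.44, mean 0.17, test down), dividing-cell markers in Col-0 (median -0.06, mean -0.04, test up), and green-tissue (median 0.18), root-hair (median 0.19) and nitrate and phosphate (median -0.10, mean 0.15) lists in bzip59, where the tests were down.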

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

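The tests of 1 deviating library, of another time of day and of later establishment were chosen only after the results were seen. 3 gene lists passed camera from limma for a different shade effect in the 2 genotypes, each with n = 3 libraries per group, and only the clock list held with an estimated correlation (adjusted p = 0.0448, against 0.451 for light signalling and for seed storage). The clock list had a median interaction of log2 0.486 and the light-signalling list 0.481, so their shade effects were more positive in bzip59, and the seed storage list had -1.571. Seed storage genes lay near the floor of the log2 scale in Col-0, so their interaction does not show a fall confined to bzip59. Removal of each library's gene length trend left medians of log2 0.20, 0.16 and -1.44 (camera from limma, adjusted p = 0.000837, 0.000837 and 0.00641), where TMM factors alone gave 0.35, 0.32 and -1.63, so the calls at the preset correlation outlasted the removal. For light signalling in white light the median was log2 -0.32, -0.17 with TMM factors and -0.11 with the length trend removed (camera adjusted p = 0.0281), the call was lost with an estimated correlation (adjusted p = 0.532), and no other explanation was tested.

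Clock genes were lower in bzip59 than in Col-0 in white light, and the median difference in shade was log2 0.14. Removal of each library's gene length trend left a camera adjusted p of 0.000198 from limma and a median of log2 -0.35, which argues against that trend as the whole cause, and 3.76e-07 to 0.0385 was the range of the adjusted p over the alternatives. Leaving out each library gave a highest adjusted p of 0.00913, without bzip59 white light 1, which argues against a single library as the cause. Another time of day at harvest stays open. Morning members were lower than evening members by log2 -0.589, at -0.82 (SE 0.12) and -0.24 (SE 0.07) against -0.16 for all genes. Only the morning set lay clearly below all genes, and the evening set was not clearly apart from them on either side, which does not decide. An effect of the bzip59 genotype on the clock also stays open and may be 1 candidate explanation, since plants had grown in continuous light and harvest times were not given.

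Seed storage transcripts were higher in bzip59 white light, with CRA1 between 7.55 and 66.7 TPM in its libraries, and the call was lost with an estimated correlation (camera adjusted p = 0.101) and with fry (0.0605). At the preset correlation leaving out each library gave a highest camera adjusted p of 4.15e-08, which argues against a single library as the cause. Leftover dry seed stays open, because 10 other transcripts stored in dry seed differed by a mean of log2 0.562 (SE 0.37), too uncertain to decide. Summed TPM of these 10 transcripts fell from library 1 to 2 to 3 in all 4 groups, as did that of the storage genes. The SE took no account of replicate number. Later establishment of bzip59 seedlings may also account for the values. On average 3 lipid-use transcripts differed by log2 0.365 (SE 0.33) in white light, which does not decide either, and by 1.004 (SE 0.33) in shade. In shade the mean log2 level of the storage genes was 1.373 ± 1.165 in bzip59 and 0.509 ± 0.099, near the floor, in Col-0. Their median difference of 0.62 is another measure than the mean of the lipid-use set. A genotype effect on storage transcripts was not tested separately.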

How the results depend on the processing

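The fits without both white-light libraries numbered 2, of protein-coding genes and with the gene length trend removed were alternatives chosen after seeing the data. Tests on counts were planned and not run because the table holds TPM. A fit of only the 2 groups compared gives no interaction. With 3 libraries per group and unknown depth, the 95% interval reached a median of log2 0.41 to either side, and 0.58 for the interaction. Of 129 recounts of called genes 97 stayed within 1.5 times, 17 were lower and 15 higher. Of 3871 list tests 3693 kept their outcome of passing or not, 98 lost a call, 76 gained one and 4 reversed. Of 68 named genes in Col-0 shade 48 kept their call in every alternative in which named genes were checked, and 55 of 68 in bzip59 shade, against 1 of 4 for genotype in white light and 1 of 7 in shade. Named genes were not checked against the absolute log2 change of at least 1. Where a cause is not given below, the cause was not tested.

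Without the filter limma called 8 genes for genotype in white light and 2 for the interaction, and with a mean of at least 5 TPM 4 for genotype in shade. Array weights gave 7597, 1058, 3 and 3484 genes for shade in Col-0, shade in bzip59, genotype in white light and genotype in shade, and 1 list for the last, with weights between 6.64e-06 and 34.7 after a fit that did not converge. An absolute log2 change of at least 1 left 767 and 675 shade genes in Col-0 and bzip59, by construction. Only the libraries of the 2 groups, with fewer samples, gave 1165, 1191, 1 and 2 genes, and bZIP59 at -2.085 in white light (limma adjusted p = 0.262) and -1.533 in shade (0.0971), against ranges over its alternatives of 0.000538 to 0.262 and 3.63e-05 to 0.105. Removal of the length trend put bZIP59 at -1.528 in shade (limma adjusted p = 0.0508). Without both white-light libraries numbered 2 the interaction had 2 genes and 5 lists, and the touch, wound and cold list reversed (camera adjusted p = 0.0499). The replicate block gave 1944, 2220, 4, 8 and 0 genes in the 5 comparisons and passed light harvesting for genotype in white light (camera adjusted p = 0.0449) and root-hair markers in Col-0 shade (0.0389), genotype in white light (0.0271) and the interaction (0.0266), while ROC4 in white light lost its call (limma adjusted p = 0.0565). Deviations of libraries with the same number correlated with a mean of 0.03, over 0.1 in 3 of 18 pairs, against -0.014 and 2 of 36 for other pairs, and 9 of 12 libraries correlated best with their own number, a hint from the data and not the design. The order of the seed storage and dry-seed sums by number, given above, is a hint of the same kind.

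With an estimated correlation 4, 4, 1, 0 and 1 lists passed in the 5 comparisons, where the preset gave 15, 14, 6, 4 and 3. Fry passed 14, 14, 3, 0 and 1. In Col-0 shade it ended the flavonoid (fry adjusted p = 0.166) and light-harvesting (0.354) calls and passed expansins (0.0023), and in bzip59 shade it ended the flavonoid (0.102) and iron (0.372) calls and passed expansins (0.0148) and PRE genes (0.000599). For genotype in white light it ended the auxin response (0.918), expansin (0.0988) and seed storage (0.0605) calls, in shade all 4 (0.0987 or more), and for the interaction light signalling (0.0512) and seed storage (0.718). With quantile normalization the clock list in white light had a camera adjusted p of 2.3e-06. The correlation of shade effects, 0.633 with a jackknife SE of 0.059, was 0.52 with a pseudocount of 0.1, 0.694 with a mean of at least 5 TPM and 0.72 in protein-coding genes.

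Leaving out each library gave ranges of 976 to 2424 genes for shade in Col-0, 871 to 3305 for shade in bzip59, 3 to 14 for genotype in white light, 5 to 9 for genotype in shade and 0 to 4 for the interaction. Lists passing ranged over 13 to 17, 13 to 15, 5 to 9, 1 to 12 and 3 to 6. BZIP59 in shade ranged from -1.632 to -1.427. For genotype in shade, auxin response (camera adjusted p 0.022 to 0.99), light harvesting (0.000194 to 0.944) and early shade (0.0476 to 0.967) reversed without bzip59 shade 2, at 0.022, 0.0476 and 0.0476.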

Other observations

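The tests of families grouped by symbol and of linkage were chosen only after the results were seen. Among 261 families of genes sharing a symbol stem, FLZ zinc finger genes, which bind the energy-sensing kinase SnRK1, fell in 6 of 14 cases in Col-0 shade and in 8 of 14 in bzip59 shade, where FLZ17 counts under 2 loci. FLZ5 was at log2 -1.67 in Col-0 and -1.55 in bzip59, and FLZ6 at -1.26 and -1.68. The family medians were -0.67 and -0.80, and camera from limma gave adjusted p = 0.00629 and 7.64e-08, and adjusted p = 1 and 0.938 with an estimated correlation. Arabinogalactan protein genes rose in 7 of 27 cases in Col-0 and fell in 1, with AGP16 at log2 1.07 in Col-0 and 0.93 in bzip59 (camera from limma, adjusted p = 0.00532, and adjusted p = 1 with an estimated correlation).

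LEA genes, which code for proteins of drying seeds and stressed tissue, fell in 5 of 8 cases in Col-0 shade and in 1 of 8 in bzip59 shade (camera from limma, adjusted p = 0.000688 and 0.00999, and adjusted p = 1 and 0.996 with an estimated correlation). LEA18 was at log2 -1.51 in Col-0 and -0.33 in bzip59, with an interaction of 1.18 (limma adjusted p = 0.586). DTX transporter genes fell in 10 of 34 cases in Col-0, with DTX21 at log2 -1.40 (camera from limma, adjusted p = 0.00469, and adjusted p = 1 with an estimated correlation). The TPS stem, which joins terpene and trehalose phosphate synthase genes, was negative in 15 of 15 cases in bzip59 white light at a median of log2 -0.60, with 0 genes called by limma and 3047 of all genes at an unadjusted p under 0.05 (camera from limma, adjusted p = 0.00313, and adjusted p = 0.966 with an estimated correlation). Ribosomal protein genes went the other way and had the smallest p among the families of that comparison, RPL genes positive in 100 of 140 cases at a median of log2 0.11 and RPS genes in 86 of 114 at 0.09, with 0 called by limma (camera from limma, adjusted p = 5.02e-15 and 5.68e-10, and adjusted p = 0.966 for each with an estimated correlation). In the interaction their medians were -0.20 and -0.18 (camera from limma, adjusted p = 6.52e-19 and 1.73e-11, and adjusted p = 0.98 for each with an estimated correlation). Log2 changes in white light had a Spearman correlation of -0.391 with gene length, and family tests were not repeated with that trend removed. Every median given kept its sign with TMM factors and with quantile normalization, while the ribosomal medians moved by over 1.5 times. In white light these were 0.28 and 0.05 for RPL and 0.25 and 0.04 for RPS, and in the interaction -0.37 and -0.12 for RPL and -0.34 and -0.13 for RPS.

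AT1G75945, AT3G57940, QQS and ROC4 were called between bzip59 and Col-0 in both lights besides bZIP59, and AT4G06665, AT1G67105 and AT1G27565 in shade alone. Linkage to the bZIP59 locus was argued against, since 0 of these 7 genes lay on chromosome 2. Duplicated or deleted segments spanning neighbouring genes were argued against as a cause shared by these genes. Their 14 nearest tested neighbours changed by a median of log2 -0.003 in the gene's own direction (SE 0.089), and 0 were called by limma. A median over all 7 genes cannot exclude such a segment at a single gene, or one confined to the gene itself. For AT3G57940, reads shared with its paralog AT1G10490 cannot be told apart from a rise of its own, because AT1G10490 differed by -1.24 TPM (SE 1.09) beside a gain of 3.56 TPM (SE 0.32). Unlinked background differences of the line may explain these genes and were not tested.

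Other splits of the same libraries were fitted. For shade in Col-0, 1 of 10 splits of the 6 libraries, the real one, gave as many as 1954 genes, and the highest other gave 1. For shade in bzip59, 1 of 10 gave as many as 2007, with a highest other of 2. For genotype, 1 of 10 splits gave as many as 5 genes in white light, with a highest other of 2, and 1 of 10 gave as many as 8 in shade, with a highest other of 3. In these 4 comparisons 10 splits are too few for a share under 0.05. For the interaction, where limma called 0 genes and 1577 had an unadjusted p under 0.05, all 100 of 100 drawn splits gave as many, with a highest other of 9, which a real count of 0 makes certain, so these splits do not bear on chance.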
